A study of Mus musculus with 6 samples.

How the data were processed

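Total RNA was measured in 6 samples of mouse embryonic fibroblasts, 2 for each of 3 labels: primary MEF, MEF transformed by H-RasV12 and Twist1, and MEF transformed by H-RasV12 and Twist2. Per the labels' protocols, RNA was extracted with an RNeasy Mini kit in duplicate, amplified and labelled with biotin using the MessageAmp II kit. The authors deposited 1 intensity per probe and array, for 36227 probes. The array's maker, the scanner, the image software, the background correction and any normalization are not given in the sources used here. The values themselves are on a linear scale without centring, from −14.6 to 35286, and the negative values show that a background had been subtracted. Whether the authors scaled the arrays to each other is unknown. Between 112 and 122 probes of an array held a code for a missing value in place of an intensity.

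Median intensities were 23.4, 18.9, 21.3, 22.4, 21.6 and 23 in the order primary MEF 1 and 2, Ras + Twist1 1 and 2, and Ras + Twist2 1 and 2. Total intensities were 8351004, 8435557, 8114781, 9528621, 8466727 and 9101473. The number of arrays limits the precision, and signal close to background limits what can be seen of dim genes, since 42.3% to 46.9% of the probes of an array lay below the floor described next.

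The deposited intensities were set to a floor of 16 and taken as log2. Log2 medians of the arrays differed by at most 0.307, less than the limit of 0.5 set for a further normalization, so none was applied. The 147 probes with a missing value on any array were dropped (108 lacked one on every array), and of the 36080 left the upper 60% by mean log2 over all 6 arrays were kept, 21648 probes. Gene symbols came from the platform's annotation table, in which 21615 probes have 1 symbol, 681 several and 13931 none. Probes with several symbols name no gene here. By gene identifier 21487 of the single-gene probes matched the RefSeq annotation of GRCm38.p6, and 0 symbols changed. For each gene the probe with the highest mean over all 6 arrays was used, which gave 12645 genes tested, of which 1629 had more than 1 probe past the filter. A log2 difference understates the change of genes whose values lie at the floor. Where several probes of a named gene passed the filter and differed, the text says so. Second probes of Ablim1, Dsp, Hmga2, Xist and Zeb2 lay below the filter, at 19.7 or less on every array, and did not follow the probe used. The second probe of Igfbp5, also below the filter, was highest on the same arrays as the probe used. It read 9.02 on primary MEF 2, 16.2 on Ras + Twist1 1 and at most 7.55 on the others.

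Groups were taken from the labels alone. For the array labelled Ras + Twist2 2 the sample title names Twist2 and the source name does not, and the title was used. Differential expression was tested with limma 3.58.1 in R 4.3.3: lmFit with 3 group means over all 6 arrays and eBayes with a trend on the mean level, on 3 residual degrees of freedom. The p-values were two-sided and adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The comparisons were transformed (the mean of both Ras + Twist labels) against primary MEF, Ras + Twist1 against primary MEF, Ras + Twist2 against primary MEF, and Ras + Twist2 against Ras + Twist1. The similarity of the Twist1 and Twist2 changes was given as a Pearson correlation and a covariance across genes, beside 1000 simulated draws of unchanged groups that share the primary MEF arrays.

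The tests of the comparisons and lists, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, save those said to be added later. The 29 lists tested cover Ras-ERK response, p53 targets, senescence inhibitors, senescence secretion, mitosis, DNA replication, epithelial-mesenchymal transition regulators, mesenchymal and epithelial markers, extracellular matrix, matrix proteases, smooth and skeletal muscle, adipocyte, bone and cartilage, macrophage, endothelial and neural genes, interferon response, MHC class I, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, unfolded protein response, NRF2 targets, Hox, imprinted, and Wnt and Notch genes. A further list of sex-specific genes was read per array only. The lists hold 951 genes, of which 949 carried a current symbol, 835 had a probe and 713 were tested, and some genes stand in several lists. Each list was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with limma's fry, and members were counted past the threshold over all genes and adjusted over the list alone. Differences between 2 arrays of a label were set against 10000 random lists matched on size and mean level.

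Genes named in the text are, by the rule, Hras, Nras, Twist1 and Twist2 among others; 13 genes of senescence and epithelial-mesenchymal transition; the genes with the largest changes past the threshold or, as here where fewer than 3 passed, the 5 with the lowest p (symbols that are only codes left out); and from each list the members with the largest differences. Others, named as examples of differences between arrays of a label, were chosen after their values were seen.

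The alternatives were quantile normalization, centring each array on its median, no filter on dim probes, a filter keeping the upper 40%, a floor of 32, log2 of the intensity plus 16, the mean of a gene's probes, every probe on its own, no trend, no moderation, only the arrays compared, a minimum fold of 2, and leaving out each array in turn. Added after the data were seen were fits without the arrays labelled primary MEF 2 and Ras + Twist1 1, centring on the probes past the filter, and the transformed arrays as 1 group. The scripts were tested on simulated data for 12645 genes with the residual spread of the labelled groups, 50 genes changed by each of 2, 4, 8 and 16-fold. Noise was drawn independently for each array, so the simulation holds no likeness between arrays of different labels. For transformed against primary MEF the numbers recovered were 0, 18, 44 and 41 of 50, with 6 false calls. For Ras + Twist1 against primary MEF they were 0, 14, 38 and 40 (4 false), for Ras + Twist2 against primary MEF 0, 15, 40 and 38 (5 false), and for Ras + Twist2 against Ras + Twist1 0, 15, 36 and 39 (5 false). With a fixed SD of 0.2 between replicates, the same design recovered 50, 47, 46 and 48 of the 50 genes changed 2-fold in these comparisons. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. No array was left out of the main results.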

Results

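Gene expression was measured on 6 microarrays of total RNA from mouse embryonic fibroblasts (MEFs), cells grown out of embryonic tissue. By their labels, 2 arrays carried RNA of primary MEFs, 2 carried RNA of MEFs transformed by H-RasV12 together with Twist1, and 2 carried RNA of MEFs transformed by H-RasV12 together with Twist2. H-RasV12 is a constantly active form of the small GTPase H-Ras, which on its own drives primary fibroblasts into senescence, a lasting arrest of growth. Twist1 and Twist2 are related transcription factors of embryonic mesenchyme that promote epithelial-mesenchymal transition. The median intensity was 23.4 and 18.9 on the arrays labelled primary MEF 1 and 2, 21.3 and 22.4 on those labelled Ras + Twist1 1 and 2, and 21.6 and 23 on those labelled Ras + Twist2 1 and 2. Total intensity ranged from 8114781 to 9528621, and between 42.3% and 46.9% of the probes of an array lay below the floor of 16. With 2 arrays per label, their number limits the precision. The labels say that RNA was prepared in duplicate. Nothing in them says that the duplicates came from separate cultures, so p-values measure only the spread between these arrays. Pearson r was 0.895 within primary MEF and 0.911 within Ras + Twist1, and 0.989 for the closest arrays of different labels. If the labels are right, this argues against repeats of 1 RNA under these 2 labels. An exchange of labels between arrays could give such a spread as well. Within Ras + Twist2 r was higher, at 0.965, but still below the 0.982 of the arrays labelled primary MEF 1 and Ras + Twist2 1. Interferon response genes (median log2 difference −0.76) and mitotic genes (0.64) differed as groups between the arrays labelled Ras + Twist2. With right labels these values too argue against repeats of 1 RNA, though part of the spread may be technical. Where 6 values are listed for a gene, they are intensities in the order primary MEF 1 and 2, Ras + Twist1 1 and 2, and Ras + Twist2 1 and 2.

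The introduced genes were examined first. Twist1 read 279.96 and 298 on the arrays labelled primary MEF, 311 and 241 on those labelled Ras + Twist1, and 232 and 244 on those labelled Ras + Twist2. Its log2 difference between Ras + Twist1 and primary MEF was −0.08 (SE 0.27), with limma's adjusted p at 1. Twist2 read 307, 659, 728, 318, 275 and 289.98, and its log2 difference between Ras + Twist2 and primary MEF was −0.67 (SE 0.53; limma's adjusted p = 0.984). Nras, a relative of the introduced Ras gene, read 453, 395, 408, 494, 375 and 471. No probe named for a single gene measured Hras, so it was not analysed here. Where the Twist probes lie relative to the introduced coding sequences is not given in the sources used here, and an introduced gene of another species or without its 3′ end can escape a probe, so these genes check no label.

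Each array was closer to an array of another label than to the array of its own label. The arrays labelled primary MEF 2 and Ras + Twist1 1 had the highest Pearson correlation of log2 intensities (r = 0.989 across 12645 genes, which are not independent replicates), and 98 genes (0.775%) differed at least 2-fold between them. Ras + Twist1 2 and Ras + Twist2 2 followed at 0.987 with 123 such genes, and primary MEF 1 and Ras + Twist2 1 at 0.982 with 267. Between arrays of the same label, r was 0.895 for primary MEF with 2413 genes (19.1%) at least 2-fold apart, 0.911 for Ras + Twist1 with 2384 (18.9%), and 0.965 for Ras + Twist2 with 787 (6.22%). The nearest array carried the same label for 0 of 6 arrays, by Pearson or Spearman correlation and after quantile normalization. The first principal component held 71.0% of the variance, with the arrays labelled primary MEF 2 at −66.7 and Ras + Twist1 1 at −65.1 and the other 4 between 30.95 and 36.1. On the second (15.9%), primary MEF 1 and Ras + Twist2 1 lay at 25.6 and 27.3, and Ras + Twist1 2 and Ras + Twist2 2 at −24.9 and −30.0. Groups were nevertheless taken from the labels in every comparison, and each direction given for a label holds for the arrays so labelled.

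**Figure D1:**
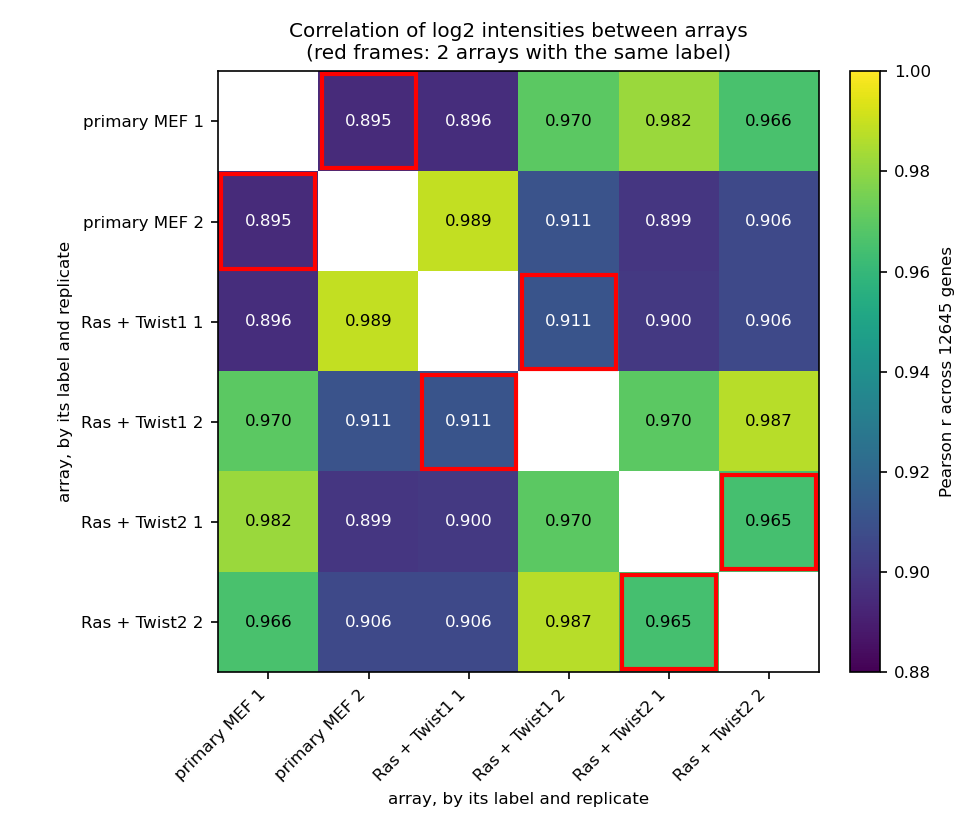
Pearson correlation of log2 intensities across 12645 genes for every pair of the 6 arrays, which stand on both axes by label and replicate, with red frames around the pairs that share a label. The same-label pairs lie at 0.895, 0.911 and 0.965, below 0.989, 0.987 and 0.982 for 3 pairs of arrays that carry different labels.

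In the transformed cells, taken as the mean of both Ras + Twist labels, genes of the matrix, of contractile cells and of leukocytes had lower median levels than in primary MEFs and genes of cell division higher ones. Mesenchymal markers had a median log2 difference of −0.63 over 28 genes measured, macrophage and leukocyte genes −0.58 over 23, smooth muscle and myofibroblast contractile genes −0.42 over 24, fibrillar collagens and extracellular matrix −0.41 over 50, Ras-ERK pathway response genes −0.37 over 25, and secreted factors of senescent fibroblasts −0.33 over 29. Mitotic cell cycle genes stood at 0.37 over 34 genes and DNA replication and E2F target genes at 0.22 over 42. All 8 lists passed limma's camera test with a preset correlation (adjusted p from 6.82e-07 to 0.0117), and all 8 calls were lost with an estimated correlation (adjusted p from 0.422 to 0.670 with an estimated correlation). Col1a2, a chain of type I collagen, had a log2 difference of −2.05 (SE 2.86) and intensities of 16.1, 4292, 3630, 13.9, 13.1 and 17.5. Actg2, a smooth muscle actin, stood at −1.79 (SE 1.71), the secreted activin subunit Inhba at −1.14 (SE 1.73), and the lysozyme gene Lyz2 of macrophages at −1.74 (SE 2.15). Cdc20, an activator of the anaphase-promoting complex, read 622, 718, 716, 1471, 640 and 1494, a log2 difference of 0.58 (SE 0.45). Each of these errors is of the size of the difference or close to it, since the arrays of a label disagree. The lower medians come from the array labelled primary MEF 2: macrophage genes deviated from the mean of the 6 arrays by a median of 1.17 there and −0.58 on primary MEF 1. Without primary MEF 2 the medians of mesenchymal and smooth muscle genes turned to 0.19 and 0.24. With Ras + Twist1 1 left out as well, a fit added after the data were seen, they were −0.15 and 0.016. Mitotic genes were high on Ras + Twist1 2 and Ras + Twist2 2 (0.52 and 0.40) and not on Ras + Twist1 1 and Ras + Twist2 1 (−0.25 and −0.27).

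Genes of the senescence arrest did not separate transformed from primary MEFs beyond the spread between arrays of a label. Cdkn1a, the cell cycle inhibitor induced by p53, read 350.3 and 1613 on the arrays labelled primary MEF, 1849 and 122 on those labelled Ras + Twist1, and 234 and 172 on those labelled Ras + Twist2 (log2 difference −1.29, SE 1.16; limma's adjusted p = 0.9999). Cdkn2a, which encodes the inhibitors p16Ink4a and p19Arf, read 582 and 50.2, then 50.6 and 603, then 472 and 528 (0.79, SE 1.29). Cdkn2b stood at −0.23 (SE 0.38) and the p53 antagonist Mdm2 at −0.38 (SE 0.42), and Trp53 had no probe named for it alone and was not analysed here. The 13 senescence-associated cell cycle inhibitors and tumour suppressors measured had a median of 0.12 and a mean of 0.04, while camera's direction was down (adjusted p = 0.917), and the 29 p53 target genes a median of −0.21 (adjusted p = 0.00325 with the preset correlation and 0.422 with an estimated correlation). Markers of epithelial-mesenchymal transition behaved alike. Fn1, which encodes fibronectin, had a log2 difference of −0.85 (SE 0.96), the intermediate filament gene Vim −0.08 (SE 0.40), Cdh2 for N-cadherin −0.27 (SE 0.35), Snai1 −0.55 (SE 0.67), Snai2 −0.22 (SE 0.37), Zeb1 0.31 (SE 0.93) and Zeb2 −0.44 (SE 0.33). Cdh1, which encodes E-cadherin, did not pass the filter, with intensities between 4.75 and 13.4 on the 6 arrays. A second probe of Zeb1 ranged only from 91.1 to 149.5, where the probe used ranged from 53.6 to 445, so the level of Zeb1 is uncertain.

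**Figure D2:**
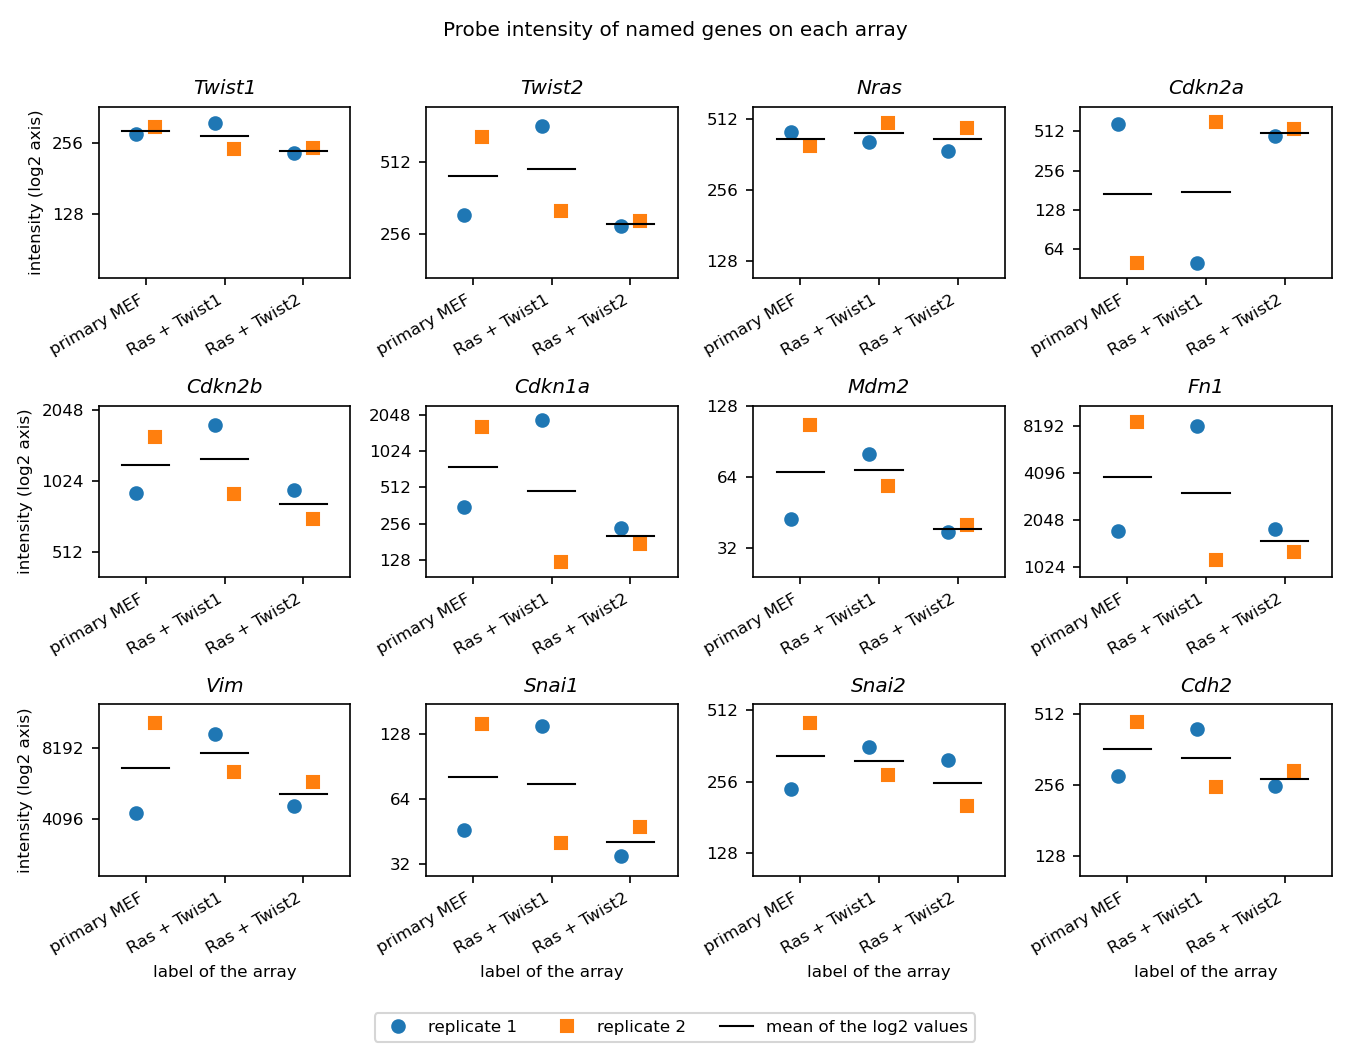
Intensity of 12 named genes on a log2 axis, by the label of the array, with circles for replicate 1, squares for replicate 2 and lines for the mean of the log2 values (n = 2 arrays per label). For Cdkn2a, Cdkn1a and Fn1 the arrays labelled primary MEF 2 and Ras + Twist1 1 lie together and apart from the others, as at 50.2 and 50.6 for Cdkn2a.

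Further gene groups were compared between transformed and primary MEFs. Lower medians with the preset correlation were found for epithelial-mesenchymal transition regulators (−0.18 over 21 genes), matrix proteases and inhibitors (−0.29 over 30), skeletal muscle genes (−0.16 over 21), adipocyte differentiation genes (−0.34 over 16), glycolysis genes (−0.15 over 25), cholesterol biosynthesis genes (−0.19 over 18), NRF2 antioxidant genes (−0.18 over 23), imprinted genes (−0.23 over 22, mean −0.58) and Wnt and Notch pathway response genes (−0.28 over 20). Oxidative phosphorylation genes (0.16 over 38) and cytosolic ribosomal proteins (0.17 over 41) had higher medians. Camera's adjusted p lay between 7.67e-05 and 0.0134 for these 11 lists with the preset correlation, and all 11 calls were lost, at adjusted p from 0.422 to 0.637 with an estimated correlation. The remaining lists did not pass: epithelial markers (0.27; adjusted p = 0.156), neural and glial genes (−0.08; adjusted p = 0.0530), MHC class I antigen presentation (median 0.09, mean 0.03, direction down; adjusted p = 0.821) and unfolded protein response genes (median −0.0041, mean 0.0044, direction down; adjusted p = 0.641). Median and mean differed in sign, with camera's direction down, for bone and cartilage genes (0.024 and −0.030; adjusted p = 0.140), endothelial genes (0.012 and −0.0022; adjusted p = 0.482), interferon response genes (0.07 and −0.09; adjusted p = 0.286) and Hox genes (0.04 and −0.02; adjusted p = 0.540). The interferon list holds Bst2, whose intensity of 35286 on the array labelled primary MEF 2 lies near 5 other probes, by number, that were bright on that array alone. Its other values were 1648, 127, 1564, 1763 and 1213.

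Of the 12645 genes tested, limma called 0 changed between transformed and primary MEFs at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 47 genes (0.372%), the smallest adjusted p was 0.9999, and 0 members of the 29 lists passed, whether adjusted over all genes or adjusted over the list alone. With camera 20 lists passed at the preset correlation and 0 at an estimated correlation, and fry called 0. Group means differed at least 2-fold for 140 genes, 37 higher and 103 lower, and the arrays did not overlap for 561 genes (4.44%, where chance gives 13.3%). The lowest unadjusted p values belonged to the folate carrier gene Slc19a1 (10.9, 15.8, 38.1, 37.4, 35.4 and 33.6; log2 difference 1.17, SE 0.22), Prl8a9 (0.96, SE 0.23), Slc10a6 (−0.82, SE 0.21), Pdzrn4 (0.87, SE 0.22) and Fndc1 (−2.03, SE 0.57), all near the floor on several arrays and none past the adjusted threshold. The probes of Pdzrn4 disagree, as both others past the filter lack this order. Simulated changes of 8-fold were recovered in 44 of 50 genes and of 2-fold in 0 of 50, at the spread of these labelled groups. The simulated noise was independent between arrays, whereas real arrays of different labels lay close together. These shares therefore do not give the power of the real comparison. Leaving out the array labelled primary MEF 2 turned the median of the secreted factors to 0.48, of extracellular matrix genes to 0.32 and of macrophage genes to 0.42. With Ras + Twist1 1 left out as well, these medians were −0.010, −0.098 and 0. This fit without both arrays that stand apart on the first principal component, primary MEF 2 and Ras + Twist1 1, was added after the data were seen. It leaves 1 array each of primary MEF and Ras + Twist1. Its residual spread comes from the arrays labelled Ras + Twist2 alone, so its calls are not read here.

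The cells labelled Ras + Twist1 were compared with primary MEFs to see the changes that accompany transformation with H-RasV12 and Twist1. No array is labelled for either gene alone, so their effects cannot be told apart. Mitotic cell cycle genes were higher (median log2 difference 0.35 over 34 genes; camera's adjusted p = 2.66e-08 with the preset and 0.886 with an estimated correlation), led by the phosphatase gene Cdc25c (0.66, SE 0.51) and the cytokinesis factor gene Ect2 (0.62, SE 0.48). Cytosolic ribosomal proteins stood at 0.19 (adjusted p = 0.000422) and oxidative phosphorylation genes at 0.11 (adjusted p = 0.0450), and these calls were lost (adjusted p = 0.886 and 0.917 with an estimated correlation). Cholesterol biosynthesis genes were lower (−0.37; adjusted p = 2.09e-06, or 0.886 with an estimated correlation), with Tm7sf2 at −0.77 (SE 0.76) and Mvd, the decarboxylase of mevalonate diphosphate, at −0.71 (SE 0.74). Interferon response genes stood at −0.30 (adjusted p = 0.000973), Ras-ERK pathway response genes at −0.25 (0.00192), skeletal muscle genes at −0.16 (0.0247), extracellular matrix genes at −0.14 (0.0317), matrix proteases at −0.11 (0.0120) and secreted factors at −0.11 (0.0477). These calls too were lost, at adjusted p from 0.886 to 0.907 with an estimated correlation, and so all 10 were lost. These medians rest on single arrays. Mitotic genes deviated from the mean of the 6 arrays by 0.52 on Ras + Twist1 2 but by −0.25 on Ras + Twist1 1, below primary MEF 2 at −0.18. Cdc25c did not follow this order. It read 18.2, near the floor, on primary MEF 1, 46.1 on primary MEF 2, and 48.2 and 43.4 on Ras + Twist1 1 and 2. Cholesterol and interferon genes stood at 0.60 and 0.70 on primary MEF 1 but at −0.28 and −0.54 on primary MEF 2. Cdkn1a stood at −0.66 (SE 1.34), Cdkn2a at 0.03 (SE 1.49), Fn1 at −0.35 (SE 1.11) and Twist2 at 0.10 (SE 0.53). Of the list members named by the rule, Bst2 had the largest difference, at −4.09 (SE 1.69). It rests on readings of 35286 on the array labelled primary MEF 2 and 127 on Ras + Twist1 1. Primary MEF 1 and Ras + Twist1 2 read 1648 and 1564. Spred2, an inhibitor of Ras signalling, followed at −1.78 (SE 1.08), then Cd74 at −1.57 (SE 1.53), Aldoc at −1.48 (SE 1.77) and Des at −1.35 (SE 0.97), with limma's adjusted p at 1 for each. Of these, Spred2, Cd74 and Aldoc were high on primary MEF 1 (189, 375 and 517) and low on primary MEF 2 (14, 6.61 and 17.5).

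Limma called 0 genes between Ras + Twist1 and primary MEF, with 38 (0.301%) at an unadjusted p under 0.05 and the smallest adjusted p at 1, and fry called 0 lists. Means differed at least 2-fold for 96 genes, 24 higher and 72 lower, and the arrays did not overlap for 1790 genes (14.2%, where chance gives 33.3%). The lowest unadjusted p values belonged to Slc19a1 (1.24, SE 0.25), Ablim1 (−1.17, SE 0.26), Prl8a9 (1.07, SE 0.27), Mbtps1 (−0.89, SE 0.25) and Adap2 (0.999, SE 0.28), whose values fall below the floor of 16 on at least 1 array. Leaving out the array labelled Ras + Twist1 1 raised the number of passing lists from 10 to 21 with the preset correlation, and quantile normalization lowered it to 6. The fit without primary MEF 2 and Ras + Twist1 1 sets 1 array against 1 array in this comparison, so its calls are not read here.

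The cells labelled Ras + Twist2 showed larger differences from primary MEFs than those labelled Ras + Twist1, in the genes of the matrix and of contractile cells. Extracellular matrix genes had a median log2 difference of −0.91, macrophage and leukocyte genes −0.81, smooth muscle and myofibroblast genes −0.78, secreted factors of senescent fibroblasts −0.72 and mesenchymal markers −0.66, with camera's adjusted p between 3.23e-08 and 2.13e-05. All 5 calls were lost, at adjusted p from 0.380 to 0.409 with an estimated correlation. These differences from primary MEF follow the array labelled primary MEF 2. That they exceed those of Ras + Twist1 also follows the array labelled Ras + Twist1 1. Extracellular matrix genes deviated from the mean of the 6 arrays by a median of 1.13 on primary MEF 2 and 1.04 on Ras + Twist1 1. They stood at −0.47 on primary MEF 1, −0.79 on Ras + Twist1 2, and −0.18 and −0.89 on Ras + Twist2 1 and 2. Col1a2 stood at −3.98 (SE 3.30), the small proteoglycan gene Bgn at −2.90 (SE 2.90; 53.7, 6591, 7190.2, 63.5, 145 and 43.9), Actg2 at −3.05 (SE 1.97), Lyz2 at −3.19 (SE 2.48), Igfbp5 at −2.79 (SE 2.21) and the fibroblast surface gene Thy1 at −2.87 (SE 2.42). Higher were DNA replication and E2F target genes (0.42; adjusted p = 0.000548), mitotic genes (0.32; 0.00126), oxidative phosphorylation genes (0.22; 0.0147) and epithelial markers (0.40; 0.0381), calls again lost at adjusted p from 0.543 to 0.732 with an estimated correlation. Epithelial markers went both ways, with the desmosome gene Dsp at 2.49 (SE 1.92), the protease inhibitor gene Spint2 at 2.16 (SE 1.62) and the keratin genes Krt19 and Krt7 at −2.08 (SE 1.34) and −0.99 (SE 0.73). Mitotic genes were high on Ras + Twist2 2 alone of these 4 arrays (0.40). DNA replication genes were low on primary MEF 2 alone of the same 4 (−0.58). Lower as well were Ras-ERK pathway response genes (−0.48), matrix proteases (−0.54), epithelial-mesenchymal transition regulators (−0.48), Wnt and Notch pathway response genes (−0.46), adipocyte genes (−0.42), p53 target genes (−0.36), NRF2 antioxidant genes (−0.33), imprinted genes (−0.22), skeletal muscle genes (−0.22), neural and glial genes (−0.13), bone and cartilage genes (−0.11) and glycolysis genes (−0.11), with adjusted p from 6.76e-07 to 0.0375. These were lost as well, at adjusted p from 0.315 to 0.380 with an estimated correlation, and so all 21 calls were lost. Cdkn1a stood at −1.91 (SE 1.34), Cdkn2a at 1.55 (SE 1.49), Fn1 at −1.36 (SE 1.11), Zeb2 at −0.87 (SE 0.38) and the transcription factor gene Prrx1 at −1.87 (SE 1.68).

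Limma called 0 genes between Ras + Twist2 and primary MEF, with 71 (0.561%) at an unadjusted p under 0.05 and the smallest adjusted p at 0.984, and fry called 0 lists. Means differed at least 2-fold for 572 genes, 221 higher and 351 lower, and the arrays did not overlap for 3091 genes (24.4%, where chance gives 33.3%). The lowest unadjusted p values belonged to Vwa2 (1.35, SE 0.29), Slc19a1 (1.11, SE 0.25), Son (−1.06, SE 0.28), Fndc1 (−2.45, SE 0.66) and Rai14 (−1.09, SE 0.30). Of these, Rai14 lay far above the floor, at 481, 646, 499, 372, 281 and 243. Leaving out the array labelled primary MEF 2 left 4 lists passing with the preset correlation, and leaving out Ras + Twist2 2 left 7. The fit without both primary MEF 2 and Ras + Twist1 1 leaves 1 primary MEF array, so its calls are not read here.

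Between the transformed lines themselves, smooth muscle and myofibroblast genes (median log2 difference of Ras + Twist2 minus Ras + Twist1 −0.73), macrophage and leukocyte genes (−0.74), secreted factors (−0.74), extracellular matrix genes (−0.67) and mesenchymal markers (−0.52) were lower under the Ras + Twist2 label, with camera's adjusted p between 0.000127 and 0.0150 with the preset correlation and 0.616 with an estimated correlation. Of the 4 transformed arrays that labelled Ras + Twist1 1 alone lay high in smooth muscle genes, whose median deviation was 0.92 there, −0.39 on Ras + Twist1 2, and −0.55 and −0.43 on Ras + Twist2 1 and 2. Higher were interferon response genes (0.50; adjusted p = 0.000255), cholesterol biosynthesis genes (0.44; 0.00773), DNA replication and E2F target genes (0.35; 0.00131), epithelial markers (0.32; 0.0487) and MHC class I genes (0.28; 0.0455), at an adjusted p of 0.616 with an estimated correlation. Among the 4 transformed arrays, interferon and cholesterol genes were high on Ras + Twist2 1 alone (0.77 and 0.45). Ras + Twist2 2 stood at −0.21 for both, below Ras + Twist1 2 at 0.04 and −0.16. MHC class I genes likewise were high on Ras + Twist2 1 (0.61), with Ras + Twist2 2 at −0.13 below Ras + Twist1 2 at −0.0098. DNA replication genes were low on Ras + Twist1 1 alone (−0.66). Ras + Twist1 2 at 0.43 lay above Ras + Twist2 1 and 2 at 0.17 and 0.40. For epithelial markers Ras + Twist1 1 and 2 stood at −0.34 and 0.16, and Ras + Twist2 1 and 2 at 0.36 and 0.27. Epithelial-mesenchymal transition regulators (−0.48), Wnt and Notch pathway response genes (−0.34), NRF2 antioxidant genes (−0.25), neural and glial genes (−0.25) and Ras-ERK pathway response genes (−0.22) completed the 15 lists that passed, at adjusted p between 0.00268 and 0.0312. All 15 calls were thus lost, these too at an adjusted p of 0.616 with an estimated correlation. The lysyl oxidase gene Lox, which crosslinks collagen, stood at −2.99 (SE 2.21; 82.5, 5617, 5297, 255, 140 and 154) in its log2 difference. Ccn5 stood at −2.87 (SE 1.55), the tight junction gene Cgn at 2.61 (SE 2.01), the interferon-induced GTPase gene Ifi47 at 1.54 (SE 1.32), Cdkn2a at 1.52 (SE 1.49) and Twist2 at −0.77 (SE 0.53).

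Limma called 0 genes between Ras + Twist2 and Ras + Twist1, with 65 (0.514%) at an unadjusted p under 0.05 and the smallest adjusted p at 1, and fry called 0 lists. Means differed at least 2-fold for 606 genes, 297 higher and 309 lower, and the arrays did not overlap for 2892 genes (22.9%, where chance gives 33.3%). The lowest unadjusted p values belonged to Vwa2 (1.35, SE 0.29), Son (−1.16, SE 0.28), Ctu2 (−1.10, SE 0.30), Mbtps1 (0.92, SE 0.25) and the interleukin-1 receptor antagonist gene Il1rn (−4.13, SE 1.13). Il1rn read 296 and 291 on the arrays labelled Ras + Twist1, 9.34 and 17.5 on those labelled Ras + Twist2, and 5.93 and 212 on those labelled primary MEF. Leaving out Ras + Twist1 1 left 8 lists passing with the preset correlation, leaving out Ras + Twist2 2 left 6, and testing without a filter on dim probes left 9. The fit without primary MEF 2 and Ras + Twist1 1 leaves 1 Ras + Twist1 array, so its calls are not read here.

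The changes under the Twist1 and Twist2 labels, each against the same primary MEF arrays, were compared across the 12645 genes, which are not independent replicates. Their log2 differences correlated at r = 0.304, with a covariance of 0.0455. Simulated unchanged groups set against those shared arrays gave r = 0.4998 (SD 0.0183) and a covariance of 0.177 (SD 0.00958) over 1000 draws, both above the observed values. Sharing the primary MEF arrays gives such an r by itself when arrays are otherwise independent. Here arrays of different labels lay close together, so the gap does not show how alike the changes are. As limma called 0 genes in either comparison, 0 were shared. A split of the primary MEF arrays would leave 1 control array per comparison and was not made. The value rests on single arrays: without Ras + Twist1 2 it was −0.522, and without primary MEF 1 it was 0.893.

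Arrays of the same label differed in whole groups of genes. Between the arrays labelled primary MEF, extracellular matrix genes were higher on replicate 2 by a median log2 difference of 1.47, with 33 of 50 genes at least 2-fold higher there, secreted factors by 1.58 (19 of 29), macrophage and leukocyte genes by 1.75 (15 of 23), smooth muscle genes by 1.196 (14 of 24) and mesenchymal markers by 1.07 (14 of 28). Interferon response genes were higher on replicate 1, with a median of −1.49 (18 of 29 at least 2-fold), as were cholesterol biosynthesis genes (−0.95; 9 of 18), MHC class I genes (−0.87; 6 of 14), DNA replication genes (−0.81; 14 of 42) and epithelial markers (−0.73; 9 of 25). Between the arrays labelled Ras + Twist1 the matrix genes went the other way by replicate number. Extracellular matrix genes were higher on replicate 1 (−1.93; 36 of 50), as were secreted factors (−1.64; 18 of 29), macrophage genes (−1.60; 14 of 23), mesenchymal markers (−1.58; 17 of 28) and smooth muscle genes (−1.39; 15 of 24). Higher on replicate 2 were DNA replication genes (1.11; 24 of 42), mitotic genes (0.79; 8 of 34) and interferon response genes (0.62; 13 of 29). Between the arrays labelled Ras + Twist2, interferon response genes (−0.76; 13 of 29), MHC class I genes (−0.65; 5 of 14), cholesterol biosynthesis genes (−0.52; 4 of 18) and extracellular matrix genes (−0.49; 17 of 50) were higher on replicate 1 and mitotic genes on replicate 2 (0.64; 2 of 34). Each of these medians lay below the 0.1 or above the 99 percentile of 10000 random lists of the same size and mean level, which describes these arrays and not their labels. Each comparison here sets 1 array against 1 array and has no replicate check.

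Across genes, the differences within primary MEF and within Ras + Twist1 correlated at r = −0.77, and of 1462 genes at least 2-fold apart within both labels 1454 went in opposite directions by replicate number. Replicate numbers name the arrays in accession order and pair nothing. Single genes show the size of these differences. Lox read 82.5 and 5617 on the arrays labelled primary MEF and 5297 and 255 on those labelled Ras + Twist1. Hmga2, a chromatin protein gene of embryonic and transformed cells, read 203, 2842, 2466, 171, 217 and 136, and Vim 4358, 10395, 9363, 6457, 4638 and 5879. The epithelial genes Spint2 (2008, 120.3, 125, 1566, 2657 and 1804) and Dsp (342, 14.4, 2.78, 385, 259.7 and 668) were lowest on the arrays labelled primary MEF 2 and Ras + Twist1 1. The keratin gene Krt19 (38.8, 290.5, 251.8, 28.2, 15.5 and 39.3) was highest there. Of 25 epithelial markers, 9 were at least 2-fold higher on primary MEF 1 than on primary MEF 2, and 3 at least 2-fold lower. Ifi47 (714, 55.4, 54.6, 222, 511 and 199) and the glycolytic aldolase gene Aldoc (517, 17.5, 9.86, 72.9, 393 and 64.2) were highest on primary MEF 1 and Ras + Twist2 1. Cdc20 was highest on Ras + Twist1 2 and Ras + Twist2 2, at 1471 and 1494.

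**Figure D3:**
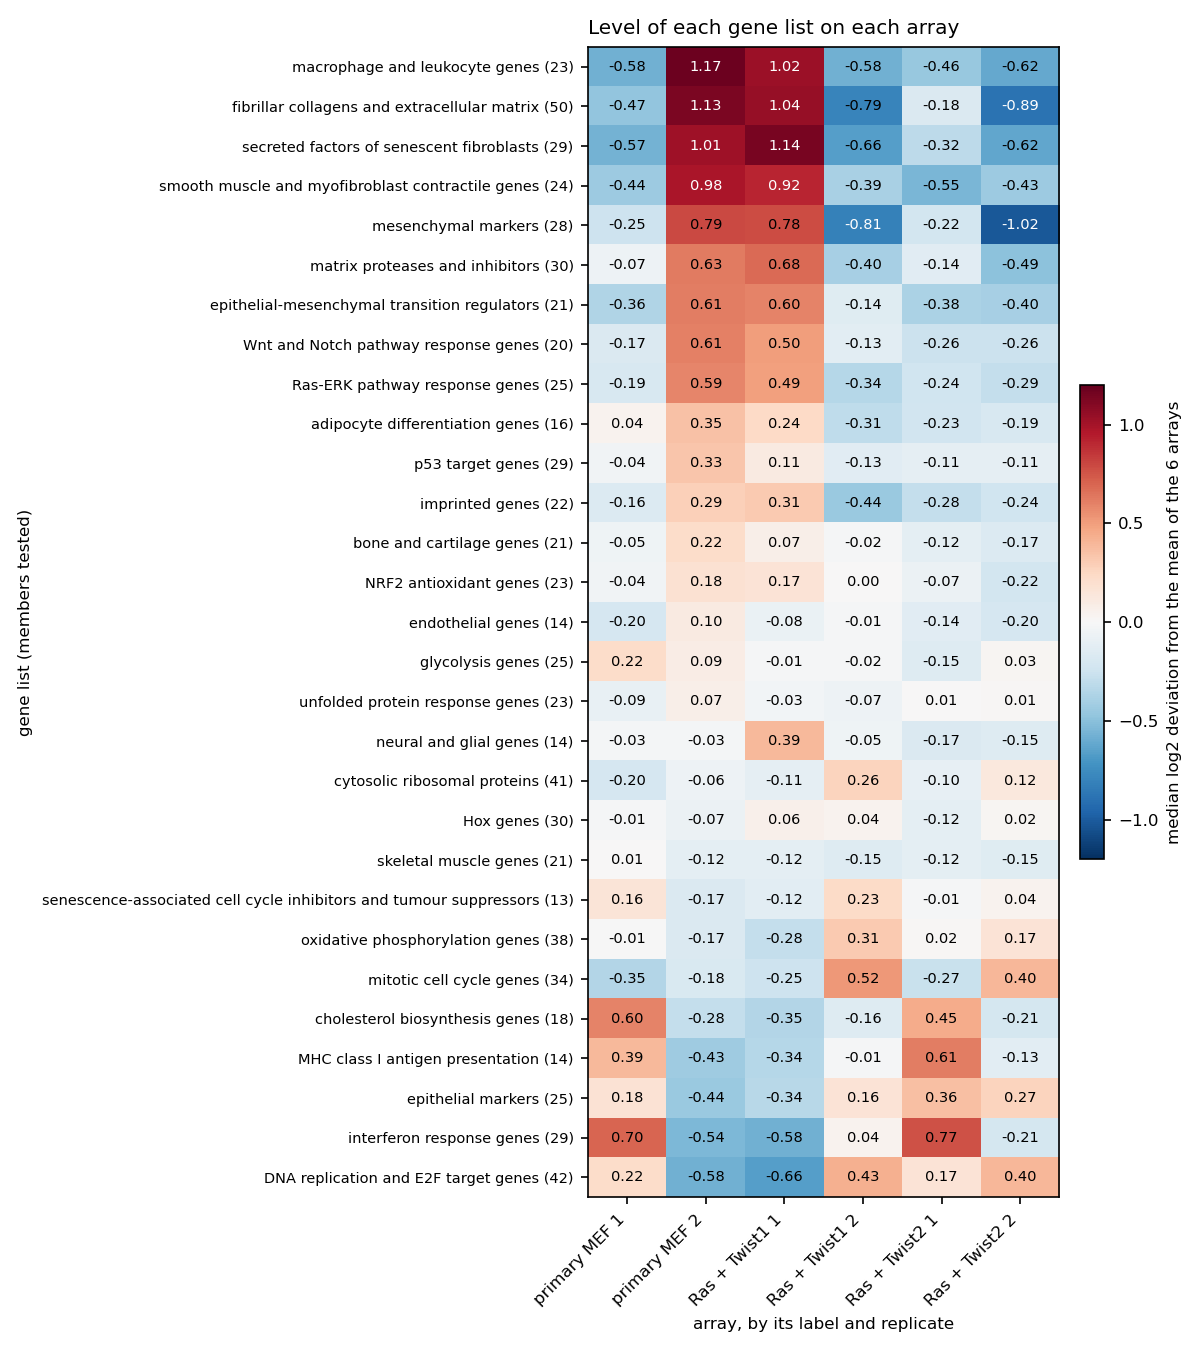
Median log2 deviation of each of the 29 gene lists, with its number of members measured, from the mean of the 6 arrays, by array. Extracellular matrix genes stood at 1.13 and 1.04 on the arrays labelled primary MEF 2 and Ras + Twist1 1 and between −0.89 and −0.18 on the other 4, interferon response genes at 0.70 and 0.77 on primary MEF 1 and Ras + Twist2 1, and mitotic genes at 0.52 and 0.40 on Ras + Twist1 2 and Ras + Twist2 2.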

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

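The named genes alone were searched for opposite orders under the Ras + Twist1 and Ras + Twist2 labels, which singled out the gene below. It had been named for a low unadjusted p in comparisons of these same arrays, which favours such an order. The order is therefore no separate support for a difference. Its second probe was looked up only after the result was seen. Mbtps1, which encodes the site-1 protease that activates sterol-regulated transcription factors, lay below both primary MEF arrays on both arrays labelled Ras + Twist1 and above them on both labelled Ras + Twist2. Its intensities were 29.6, 29.7, 11.9, 13.0, 30.04 and 30.3, and the difference of Ras + Twist2 minus Ras + Twist1 was 0.92 on the log2 scale (SE 0.25, limma's adjusted p = 1). With no filter the adjusted p was 0.0208 and with no moderation 0.00345. Both arrays labelled Ras + Twist1 lay below the floor of 16, and the values of Ras + Twist2 exceeded those of primary MEF by less than 1 intensity unit. A second Mbtps1 probe, below the filter, read 14.9, 6.17, 5.73, 17.5, 13.8 and 13.4 and had no such order.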

How the results depend on the processing

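The fits without the arrays labelled primary MEF 2 and Ras + Twist1 1, with centring on probes past the filter, or with the transformed arrays as 1 group were chosen only after the results were seen. Limma's count of 0 genes in each comparison became 3, 1, 3 and 6 with no filter (transformed, Ras + Twist1 and Ras + Twist2 against primary MEF, then Ras + Twist2 against Ras + Twist1), 1 with a floor of 32 in all but Ras + Twist1 against primary MEF, and 2, 1, 1 and 2 with no moderation. These genes, Ankrd34c, Gpr157, Fes, Eri2, Ucn, Mbtps1 and a code-named transcript, lie near the floor. Leaving out 1 array gave 0 to 2 genes for transformed against primary MEF, and 0 in the other comparisons. The 2, without primary MEF 2, were Ercc2 and Samd3, each bright on 1 array alone. Such fits assume that a lone array varies like the other groups. The other alternatives gave 0 genes. The correlation of the Twist1 and Twist2 changes was 0.275 with quantile normalization, 0.275 for the upper 40% of probes, 0.334 for every probe and 0.760 without both arrays, and −0.522 to 0.893 on leaving out 1 array. All lists lost camera's call with an estimated correlation (0 in each comparison) or with fry (0). In the order above, 20, 10, 21 and 15 lists passed, 6 with quantile normalization in the Ras + Twist1 comparison, 9 with no filter between the Ras + Twist labels, and 7, 7, 3 and 8 without both arrays. Leaving out 1 array gave 4 to 22, 9 to 21, 4 to 23 and 6 to 17.

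Of 435 list medians for transformed against primary MEF under alternatives, 92 no longer passed and 3 newly passed without changing sign. A further 24 changed sign with a call before or after, and these may have lost or gained the call too. Without both arrays the sign changed for epithelial-mesenchymal transition regulators (0.044), smooth muscle (0.016), interferon response (−0.39), imprinted genes (0.0031), epithelial markers (−0.12), MHC class I (−0.22), senescence inhibitors (−0.081) and unfolded protein response (0.045). On leaving out 1 array, medians ranged from −0.68 to 0.046 for Ras-ERK response, −0.36 to 0.0077 for p53 targets, −1.10 to 0.48 for secreted factors, −0.16 to 0.63 for DNA replication, −0.74 to 0.26 for epithelial-mesenchymal transition regulators, −1.06 to 0.19 for mesenchymal markers, −1.41 to 0.32 for extracellular matrix, −1.17 to 0.24 for smooth muscle, −0.29 to 0.058 for skeletal muscle, −0.20 to 0.046 for bone and cartilage, −1.32 to 0.42 for macrophage, −0.089 to 0.035 for neural, −0.61 to 0.46 for interferon response, −0.41 to 0.42 for MHC class I, −0.63 to 0.23 for cholesterol synthesis, −0.42 to 0.17 for imprinted, −0.69 to 0.040 for Wnt and Notch, −0.16 to 0.17 for senescence inhibitors, −0.13 to 0.53 for epithelial markers, −0.067 to 0.17 for endothelial, −0.041 to 0.13 for unfolded protein response and −0.025 to 0.085 for Hox genes. The other lists kept their sign on leaving out 1 array. Leaving out primary MEF 1 or 2 moved most of these, as the arrays of that label differ from each other. Of 2329 values of named genes, 3 were called, all of Mbtps1, and 147 changed sign, 105 of them on leaving out 1 array. For the other changes with filter, floor, moderation and normalization the cause was not tested. Signal close to background limits the calls that depend on filter and floor.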

Other observations

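The nearest-array test, the scaling test and the test of an area of the array surface were chosen only after the results were seen, as were the genes of the next paragraph. The test of the differences within the closest pairs uses pairs that the data gave, though its prediction was written before its r was seen.

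Across all arrays, without reference to labels, the genes of largest spread included a few imprinted genes, which are expressed from only the maternal or the paternal copy, beside matrix genes such as Col1a2 and Bgn. Other imprinted genes, such as Plagl1 (125 to 165), varied little, and the list was not tested for its spread. The growth factor gene Igf2 read 5.80, 5081, 4627, 7.89, 18.7 and 11.8 in the array order of the report (SD 4.23 on the log2 scale). Its neighbour H19 read 54.7, 6023, 6456, 56.4, 51.6 and 73.7, and the noncoding gene Rian 11.1, 2035, 1815, 3.36, 2.86 and 5.90. The adaptor gene Grb10 read 6.69, 7595, 7049, 1.90, 12.4 and 19.6 (SD 4.53), while its second probe, higher on the same 2 arrays but by far less, read 32.6, 69.9, 69.97, 34.9, 30.7 and 32.6. The Y-linked gene Eif2s3y read 173 on both arrays labelled primary MEF 2 and Ras + Twist1 1 and at most 7.64 on the other 4. Xist, transcribed from the inactive X chromosome, read 211, 92.5, 137, 207, 178 and 317, lowest on the same arrays. The Y-linked Kdm5d read 54.2, 62.7, 76.9, 67.4, 59.3 and 69.3, without such a gap, and Uty at most 11.6 on any array. Only Eif2s3y thus showed a wide gap between these 2 arrays and the other 4. Xist was lower on the 2 arrays but still read 92.5 and 137 there, against 178 to 317 on the other 4. Kdm5d did not follow Eif2s3y. Uty lay below the floor on every array, so its lack of a difference shows nothing. These genes therefore do not settle whether the cells differ in sex, and the labels name no sex, culture or embryo to compare them with.

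Every array was nearest to an array of another label, for which an exchange of labels between arrays, a culture or batch shared by close arrays, and scaling were weighed. An exchange could give this pattern, though the count of 0 of 6 arrays nearest to their own label, in 3 mutual pairs, is the pattern itself and speaks for no explanation. Labels that are right for all arrays together with a transformation effect alike in every culture would tie the differences within the closest pairs together. The Ras + Twist2 minus primary MEF difference would follow the sum of the other 2 differences. Across 12645 genes, which are not independent replicates, r was −0.0322 (bootstrap −0.0531 to −0.0148). Each difference is 1 array minus 1 array, so this interval holds no spread between arrays. Simulations gave 0.236, 0.446 and 0.622 for 4-fold effects in 200, 500 and 1000 genes and 0.282 for 2-fold effects in 1000. These pairs were taken as the most alike, and after quantile normalization 247, 122 and 113 genes differed at least 2-fold within them. As 122 and 113 lie below every simulated number of genes, effects of that extent were absent before r was computed. This r of −0.0322 therefore does not decide on right labels with cultures or batches shared across them. Effects smaller, in fewer genes or particular to a culture stay open. Scaling is argued against, as 0 of 6 arrays were nearest to their own label after quantile normalization. Of the 15 splits of the arrays into 3 pairs, too few for a share under 0.05, the labelled split called 0 genes by limma's F-test, a count that any split must match, and the highest other, that of the 3 closest pairs, called 6754, which restates the structure of the samples and says nothing of which labels, if any, are wrong; no array was moved to another group.

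Single probes were far brighter on 1 array than on the other 5 in 29 cases, for which a defect of the spot, a defect of an area of the array surface, and transcripts present in a single culture were weighed. On the array labelled primary MEF 2, 6 of its 7 such probes lie close by probe number, among them those of Bmpr2, Abca4, Clca3b, Apcdd1 and Bst2 (permutation p = 1e-05, the smallest that 100000 permutations can give). The area holds 16 probes, of which these 6 and no others were brighter than on every other array, which is consistent with a defect of part of an area if probe numbers give positions, an assumption not stated in the sources used here. For the scattered cases, such as Ercc2 at 9718 on primary MEF 1 and Ulk2 at 24097 on Ras + Twist2 2, a spot defect and a transcript of a single culture could not be told apart. Another probe of the gene rose in 0% of the 3 cases that have one (exact interval up to 70.8%), of which Apcdd1 and Clca3b lie in that area and only Rinl is a scattered case.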
